A study of Mus musculus with 19 samples.

How the data were processed

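RNA from 19 preparations of mouse neutrophils was measured on 1-colour Illumina BeadChip arrays, 1 array per preparation. The groups came from the sample titles: naive neutrophils from bone marrow (NN, n = 7), splenic neutrophils of tumour-bearing mice (G-MDSC, granulocytic myeloid-derived suppressor cells, n = 4), tumour-associated neutrophils (TAN, n = 3, numbered 1, 2 and 4) and TANs after treatment with SM16, an inhibitor of the Alk5 kinase of the TGF-beta receptor (SM16, n = 5). Per the labels, the RNA was amplified and labelled with biotin. The treatment and extraction protocols in the labels describe fixed and embedded tissue biopsies, which are not neutrophils, so nothing was taken from them. Nothing in the labels says that replicates came from separate animals, so the p-values measure only the spread between samples.

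The deposited table that is not normalized holds the mean bead signal of 25697 probes as an intensity on a linear scale, exported from GenomeStudio (version not stated), with no background subtracted. Beside each signal stands a detection p-value, which the deposited values show to be the share of the array's negative controls (756 to 788 per array) above the probe. The authors also deposited an intensity table of 17004 probes on a linear scale with identical medians and upper quartiles on every array, as quantile normalization gives. Their series table holds the same values (largest difference 0).

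The signals that were not normalized were background corrected, quantile normalized and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, with the background read from the detection p-values and an offset of 16. Probes with a detection p-value under 0.01 on 3 or more arrays were kept (13945). Of these, 13088 carried a gene symbol in the annotation at hand, which names only probes of the normalized table, and 857 had none and were left out. Each gene was represented by its probe with the highest mean over all arrays, which gave 9523 genes, 2522 of them with 2 or more probes past the filter. Array depth is given as the number of detected probes, and the number of arrays limits the precision.

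The 4 groups were fitted in a single linear model per gene with limma (15 residual degrees of freedom, variance trend on), and 5 differences between groups were tested on both sides: SM16 minus TAN, TAN minus NN, SM16 minus NN, G-MDSC minus NN and TAN minus G-MDSC. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Every limma p below is adjusted in this way. All 4 groups share 1 estimate of spread per gene, drawn mostly from NN, G-MDSC and SM16. Across genes, arrays of a group correlated at 0.881 or more in TAN and at 0.956 or more in each other group. Where the TAN arrays vary more, p-values of comparisons with TAN understate that spread. A fit of only SM16 and TAN called 2365 genes instead of 4380. The TAN arrays also enter the spread used where TAN is not compared. Fits of only the 2 groups called 6746 genes instead of 6146 in SM16 minus NN and 5132 instead of 4373 in G-MDSC minus NN. Levels are mean log2 intensities ± SD. Where the arrays of the dimmer group with a detected signal did not outnumber those without, the text gives a bound, "at least N-fold": the bright group's mean over the dim group's mean, with each array of the dim group raised to the lowest value of a detected probe on that array. Folds and bounds are on the background-corrected scale, and a bound is no floor for other processing. Without background correction 830 instead of 1944 genes were called at 2-fold or more in SM16 minus TAN.

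Before the data were examined, 34 gene lists were fixed, 11 of them markers of other cell types and of granulocyte precursors. Some lists share members, so their results are not independent. Granulocyte precursor markers share Mpo, Camp, Ngp and others with granule proteins, and Top2a and Mki67 with cell cycle genes. Each list was tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the 34 lists of a comparison, and again with an estimated correlation. With the preset correlation camera called 3, 25, 25, 23 and 18 lists in the 5 comparisons in the order above, and with an estimated correlation 0, 12, 14, 8 and 5. Results for single genes were named by a rule fixed at the same time: the 15 called genes with the largest rise and the 15 with the largest fall in SM16 minus TAN, 10 and 10 in each other comparison, up to 4 called members per list with the largest change, and Ccl17, Ccl2, Ccl5, Ccl3, Tnf, Icam1, Ly6g, S100a8, Arg1 and Mpo whatever their values. Genes named by size had no overlap between the arrays of both groups, had detected signal on every array of the higher group, and had a gene name rather than a clone name, which passed over 1 symbol. Ly6g was on the list of genes to report but had no probe among those tested.

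The fit, the calls and the list test were run on simulated gene values with 200 changed genes among 9523 in each comparison. The other members of the NF-kB list were raised by 1 log2 as well. In SM16 minus TAN, 19.4% of 67 genes changed by 0.5 log2 were called, 71.6% of 67 changed by 1 and 97.0% of 66 changed by 2. The shares were 26.9%, 73.1% and 93.9% in TAN minus NN, 50.7%, 94.03% and 100% in SM16 minus NN, 23.9%, 85.1% and 100% in G-MDSC minus NN, and 20.9%, 65.7% and 97.0% in TAN minus G-MDSC. Unchanged genes made up 9.03%, 3.27%, 3.17%, 5.85% and 4.83% of the genes called, the raised list members included. The raised list passed camera at the preset correlation in every comparison (adjusted p of 3.14e-40 or less). Among lists without its raised members 1 was called in G-MDSC minus NN and 0 in each other comparison. The simulated spread came from NN, G-MDSC and SM16, so it does not hold the spread between the TAN arrays. Background correction, normalization, the filter and the choice of probe were not part of the simulation. Its genes varied independently, and fewer were changed than were called in the data.

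Alternatives planned beforehand were other normalizations (none of the background, median scaling, the authors' table), other filters, the mean of a gene's probes, array weights, only the 2 groups compared, the replicate number as a block, and each array left out in turn. TAN replicate 4 alone, the array batch described with the results, median scaling for single genes and lists, and bounds where some arrays of the dimmer group were detected were added after seeing the data. Figures were drawn with matplotlib 3.10.9.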

Results

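The arrays compared neutrophils of marrow, spleen and tumour, and tumour neutrophils with and without inhibition of TGF-beta signalling. Detected probes numbered 10660 to 11807 on the 7 NN arrays, 11283 to 11435 on the 4 G-MDSC arrays, 9599 to 10773 on the 3 TAN arrays and 10880 to 12492 on the 5 SM16 arrays, of 25697. The lowest signal on an array was 10.3 to 17.7 on NN replicates 6 and 7 and all G-MDSC arrays, and 47.5 to 65.5 on the others, which marks a batch that the labels do not name. All TAN and SM16 arrays lie in the second batch and all G-MDSC arrays in the first.

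TAN replicates 1 and 2 stood apart from TAN replicate 4 in a way that split probes of the same gene. Among 324 genes with at least 2 bright probes, the difference between the probes lay more than 2 log2 from its mean on the SM16 arrays for 28.4% of genes on TAN replicate 1 and 27.2% on TAN replicate 2. No other array exceeded 1.54%, and TAN replicate 4 had 0. Across genes, which are not independent replicates, TAN replicate 4 correlated with TAN replicates 1 and 2 at r = 0.881 and 0.891 and with the SM16 arrays at 0.964 to 0.976. Results on TANs were therefore also computed with TAN replicate 4 alone, a single array that is assumed to vary like the other groups. Changes of a call or direction are given. That array is also part of the fits with all TAN arrays, so agreement between both is partly built in. For genes named for no overlap between the arrays, the direction with it is fixed beforehand.

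**Figure D1:**
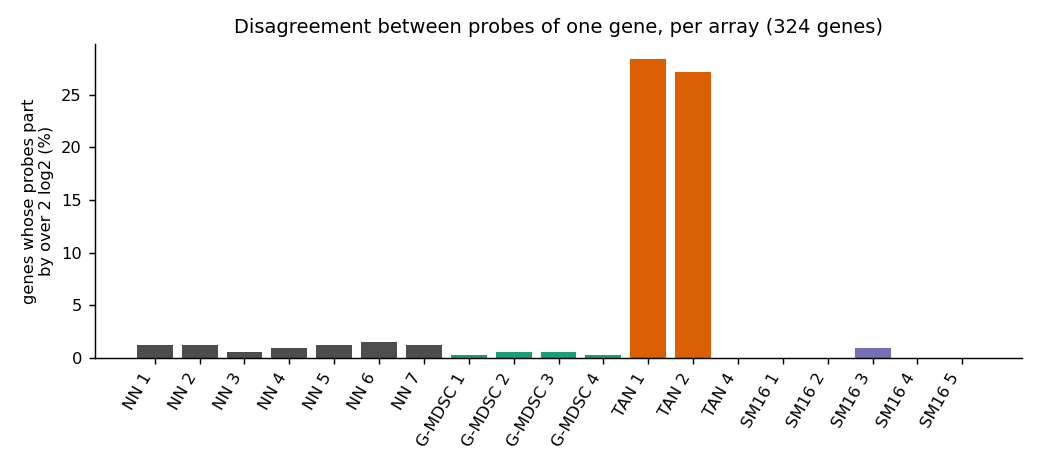
Percent of 324 genes whose probes part by over 2 log2, per array, with bars coloured by group. TAN replicates 1 and 2 stand at 28.4% and 27.2%, and no other array exceeds 1.54%.

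SM16 minus TAN asks how tumour neutrophils differ when the TGF-beta receptor kinase is inhibited. Ccl17, a chemokine that draws regulatory T cells through Ccr4, was at least 35.05-fold lower in SM16-treated TANs (4.63 ± 0.13, SD, n = 5) than in TANs (10.49 ± 1.09, SD, n = 3; limma adjusted p = 7.53e-10). The gene lies on chromosome 8 from 94809380 to 94812038 in the GRCm38 mouse genome. Cxcl13, a chemokine that draws B cells (chromosome 5, 95956939 to 95961068), rose 23.9-fold, from 8.98 ± 1.04 to 13.56 ± 0.13 (adjusted p = 9.6e-08). Clec10a, a lectin of alternatively activated myeloid cells, rose 5.33-fold to 12.56 ± 0.24, and Vcam1, an adhesion molecule, rose 6.42-fold to 12.74 ± 0.22. For each of these genes no SM16 array overlapped a TAN array. The log2 changes with TAN replicate 4 alone were -4.61, 3.40, 2.52 and 1.66, and all 4 genes remained called.

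Several other genes were lower in the SM16 preparations with all TAN arrays and with TAN replicate 4 alone. Which cells of the preparations held these transcripts, or those of Ccl17, Cxcl13, Clec10a and Vcam1, was not tested. Bdh2, a dehydrogenase, fell 14.7-fold (log2 change -3.87, SE 0.23; -3.15 with TAN replicate 4 alone), and Slc9b2, a sodium-proton exchanger, was at least 7.27-fold lower (-2.82 log2 with TAN replicate 4 alone). Olfml3, a secreted olfactomedin-like protein, was at least 7.63-fold lower (detected on 1 of 5 SM16 arrays; -3.26 log2 with TAN replicate 4 alone). Itgae, the integrin CD103, fell 6.94-fold (-2.80, SE 0.31; -1.90), and Ccr6, the receptor of Ccl20, was at least 3.97-fold lower (-2.14 log2 with TAN replicate 4 alone). Ifnb1, the type I interferon beta, was at least 5.10-fold lower (-2.11 log2 with TAN replicate 4 alone) and Havcr2, the inhibitory receptor Tim-3, fell 5.51-fold (-2.46, SE 0.25; -2.23). Ctsk, a collagen-cleaving cathepsin, Ptgs2, the inducible cyclooxygenase, and Vegfa, an angiogenic growth factor, fell 5.49-fold, 3.21-fold and 2.83-fold (-2.33, -1.76 and -1.15 with TAN replicate 4 alone). Of the 15 genes named for the largest fall, 11 were also called with TAN replicate 4 alone.

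The genes that rose most after SM16 were largely structural genes of hair. Of the 15 named for the largest rise, 10 belong to the hair follicle, among them S100a3, a calcium-binding protein of the hair cuticle, which rose 40.8-fold (11.68 ± 1.497 against 6.33 ± 0.35), and the hair keratins Krt33a, which rose 20.4-fold, and Krt31, at least 17.5-fold higher. These 3 changed by 5.12, 4.30 and 5.33 with TAN replicate 4 alone. The median of the 10 genes differed between the SM16 arrays from 7.11 to 11.60, and its highest value on a TAN array was 5.19. Endothelial markers rose too, 7 of 12 measured (adjusted over the list alone also 7) and none fell. Their median change was 1.51, or 1.22 with undetected members at their bounds (camera adjusted p = 9.02e-05, adjusted p = 0.704 with an estimated correlation). Plvap, a protein of fenestrated endothelium, was at least 4.85-fold higher and Esam, an adhesion molecule of endothelial cells and platelets, rose 5.72-fold. On TAN replicate 4 alone 5 endothelial markers rose and the list passed camera as higher at the preset correlation (median 0.91, adjusted p = 3.74e-06, adjusted p = 0.477 with an estimated correlation). Against naive neutrophils the list was lower in TANs at the preset correlation (adjusted p = 0.00907, adjusted p = 0.339 with an estimated correlation) and had no call after SM16.

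Tnf and Icam1, an inflammatory cytokine and the adhesion ligand of neutrophil integrins, depended on which TAN arrays were used. Tnf rose 4.00-fold, from 11.72 ± 1.92 to 13.72 ± 0.27 (adjusted p = 0.00662), but TAN replicate 4 stood at 13.93 and alone gave a change of -0.21 (adjusted p = 0.890). Icam1 rose 3.36-fold (adjusted p = 0.00304) and gave -0.17 with TAN replicate 4 alone (adjusted p = 0.810). Ccl3 and Ccl2, chemokines for monocytes and T cells, rose 2.67-fold and 4.42-fold, against 0.04 and 0.49 log2 with TAN replicate 4 alone, which ended both calls. The Ccl3 probe read 89.4% of the highest signal of its array on TAN replicate 4 and 91.9% to 95.2% on the SM16 arrays, so near the top of the scale that a difference between these arrays cannot be read from it. The Tnf call was also lost without TAN replicate 1 (1.40, adjusted p = 0.0816) or TAN replicate 2 (1.49, adjusted p = 0.0713), and so was that of Ccl3 (1.14 and 1.01). The Ccl3 call was also lost with median scaling (1.08, adjusted p = 0.0650) and the replicate block (1.29, adjusted p = 0.0569). Arg1, the arginine-degrading enzyme, rose 1.96-fold with all arrays, by 0.64 and 0.73 log2 short of the threshold without TAN replicates 1 and 2 and by 0.65 with median scaling (adjusted p = 0.0882), and gave -0.17 with TAN replicate 4 alone. Ccl5 changed by -0.76 (SE 0.36, adjusted p = 0.0924), past the threshold without TAN replicate 4 (-1.13), and S100a8, a calcium-binding protein of neutrophils, by 0.03 (SE 0.10), a sign that turned with median scaling (-0.26), with TAN replicate 4 alone (-0.07) and without TAN replicate 1 (-0.01). Mpo, the myeloperoxidase of azurophil granules, was at least 2.25-fold lower (adjusted p = 0.00183). With TAN replicate 4 alone Mpo changed by -1.20 log2, without a call. It lost its call without background correction (adjusted p = 0.0867) and in the authors' table (adjusted p = 0.0614).

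**Figure D2:**
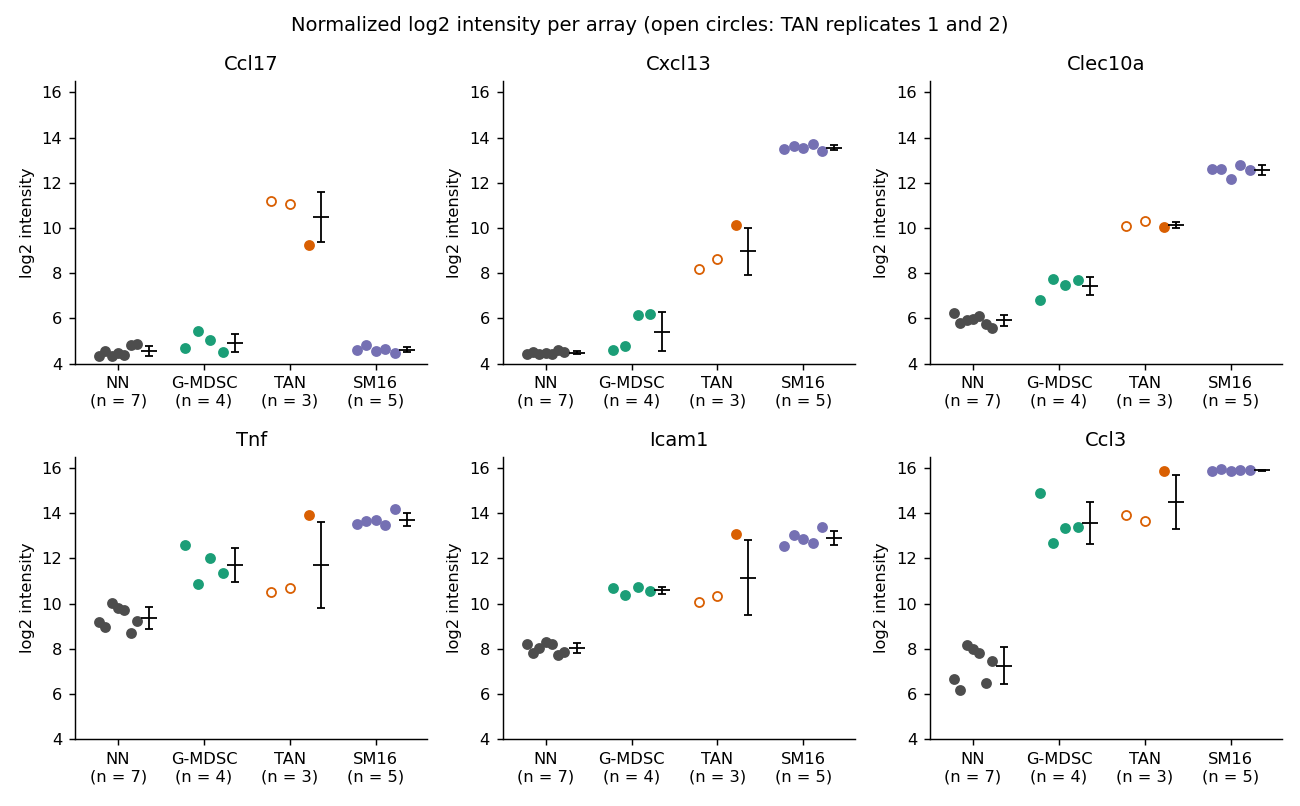
Normalized log2 intensity of 6 genes per array (vertical axis) in the 4 groups, with group mean and SD as bars and TAN replicates 1 and 2 as open circles. Ccl17 was at 9.23 or more on the TAN arrays and 4.63 ± 0.13 after SM16, while Tnf and Icam1 on TAN replicate 4 lay near the SM16 arrays, as did Ccl3, which was near the top of the scale.

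Among the gene lists, class I antigen presentation rose with all TAN arrays: 12 of 19 members rose and 3 fell (the same counts adjusted over the list alone), with a median change of 1.36 (camera adjusted p = 0.00151, adjusted p = 0.704 with an estimated correlation). H2-K1, a class I heavy chain, rose 9.26-fold, but TAN replicate 4 stood at 13.68 against 13.74 ± 0.16 after SM16. With that array alone no member was called and the median change was 0.02. Macrophage and monocyte markers had 12 of 16 members up and 1 down (12 and 1 adjusted over the list alone), with a median change of 1.44 (camera adjusted p = 1.04e-05, adjusted p = 0.704 with an estimated correlation) and 0.60 with TAN replicate 4 alone, where 1 member rose, 2 fell and the list passed camera as higher (adjusted p = 0.0126, adjusted p = 0.789 with an estimated correlation). C1qa, a chain of complement C1q, rose 17.5-fold with all arrays and gave 0.56 log2 with TAN replicate 4 alone (adjusted p = 0.375).

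Camera called 3 of 34 lists at the preset correlation of 0.01 and 0 with an estimated correlation. On TAN replicate 4 alone, a single-array group, the numbers were 11 and 0. Each list call given for that array thus rests on the preset correlation. These other lists did not pass camera with all arrays. Of 24 chemokine ligands 11 rose and 5 fell (11 and 5 adjusted over the list alone; camera adjusted p = 0.133), and with TAN replicate 4 alone 2 rose and 2 fell. Of 33 cytokines and growth factors 6 rose and 15 fell (6 and 17 adjusted over the list alone; camera adjusted p = 0.366). Of 30 members of the TGF-beta pathway and response 4 rose and 9 fell (4 and 8 adjusted over the list alone; camera adjusted p = 0.670), with Runx1, a transcription factor that partners Smads, down 3.81-fold (-1.93, SE 0.27; -1.36 with TAN replicate 4 alone). NF-kB targets had 3 up and 10 down of 24, and immediate early genes 3 up and 10 down of 31 (3 and 10, and 3 and 8, adjusted over each list alone; camera adjusted p = 0.754 and 0.512). Class II presentation had 0 up and 4 down of 16 (0 and 4 adjusted over the list alone, camera adjusted p = 0.366). It passed as lower with median scaling at the preset correlation (adjusted p = 0.0364), and an estimated correlation was not run there. At the preset correlation and with TAN replicate 4 alone cytokines, NF-kB targets, immediate early genes and class II presentation passed as lower (adjusted p = 0.000499, 0.0126, 0.00913 and 0.00438). None of them did with an estimated correlation (adjusted p = 0.322, 0.628, 0.628 and 0.615). Cytokine and chemokine receptors had 9 up and 10 down of 30 (10 and 10 adjusted over the list alone; camera adjusted p = 0.3997), with a median of 0.17 that turned to -0.09 with median scaling, to -0.026 without a filter and to -0.34 with TAN replicate 4 alone, where they passed as lower (adjusted p = 0.0381, adjusted p = 0.477 with an estimated correlation). Fibroblast markers had 4 up and 1 down of 12 (4 and 1 adjusted over the list alone; median 0.42, or 0.25 with members at their bounds; camera adjusted p = 0.133) and passed as higher with TAN replicate 4 alone (median 0.72, adjusted p = 0.0162, adjusted p = 0.729 with an estimated correlation). Interferon-stimulated genes had 6 up and 11 down of 39 (the same counts adjusted over the list alone), with a median of -0.08, a mean of 0.05 and an upward camera test (adjusted p = 0.773), and passed as lower with TAN replicate 4 alone (median -0.34, adjusted p = 0.00818, adjusted p = 0.905 with an estimated correlation). Of 40 cytosolic ribosomal proteins 11 rose and 3 fell (11 and 3 adjusted over the list alone), with a median of 0.04 that turned to -0.21 with median scaling (camera adjusted p = 0.0516, adjusted p = 0.930 with an estimated correlation). That list passed camera without TAN replicate 2 or 4 or SM16 replicate 1, 3 or 4 (adjusted p from 0.0238 to 0.0487), with a median of -0.04 without TAN replicate 4. It also passed without background correction, in the authors' table, without a filter and with the replicate block (adjusted p = 0.0415, 0.0464, 0.0398 and 0.0377), all at the preset correlation. Lysosomal genes had 11 up and 5 down of 31 (11 and 5 adjusted over the list alone, camera adjusted p = 0.104). Their median of 0.04 turned to -0.25 with median scaling and to -0.05 without TAN replicate 4. They passed as higher without TAN replicate 2 at the preset correlation (0.10, adjusted p = 0.0359), and an estimated correlation was not run there. With TAN replicate 4 alone their median was 0.25, called at the preset correlation but not with an estimated one. Oxidative phosphorylation had 13 up and 12 down of 57 (13 and 12 adjusted over the list alone), with a median of -0.06 and an upward camera test (adjusted p = 0.3997). Its median turned to 0.06, 0.04 and 0.01 without TAN replicate 1, TAN replicate 2 and SM16 replicate 1, and to 0.11 with TAN replicate 4 alone, where the list passed as higher (adjusted p = 0.0180, adjusted p = 0.905 with an estimated correlation). T and NK cell markers had 1 up and 4 down of 13 (1 and 2 adjusted over the list alone; median -0.60, camera adjusted p = 0.773), and a median of 0.00 with TAN replicate 4 alone.

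In total 4380 of 9523 genes were called between SM16 and TAN, 1696 up and 2684 down, and 5114 had an unadjusted p under 0.05. At 2-fold or more the counts were 1089 up and 855 down, a majority that turned without TAN replicate 4 (1463 up and 1799 down) and with TAN replicate 4 alone (125 up and 161 down). It was also gone in a fit of only the 2 groups (723 up and 725 down) and with array weights (1433 up and 1793 down). Of 2522 genes with several probes, 276 (10.9%) had probes called in opposite directions. The direction of such calls rests on the probe kept. The arrays of the 2 groups did not overlap for 23.6% of genes, where chance gives 3.57%. TAN replicate 4 alone called 451 genes, 205 up and 246 down, of which 143 and 194 were called the same way with all arrays, and 19.4% of the calls made with all arrays had the opposite sign with it. Without TAN replicate 1 the count was 2276 and without TAN replicate 2 it was 2424, and without TAN replicate 4 the count at 2-fold or more was 3262 instead of 1944.

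TAN minus NN asks how neutrophils in the tumour differ from naive neutrophils of the marrow. Chemokine genes were among the most raised in TANs. Ccl12 and Ccl7, chemokines for monocytes, were at least 356-fold and at least 231-fold higher (13.92 ± 0.13 and 13.30 ± 0.34, n = 3, against 4.83 ± 0.25 and 4.61 ± 0.20, n = 7), and Ccl4 rose 431-fold, to 90.3% to 94.6% of the highest signal of each TAN array, where the scale limits the fold. Cxcl1 and Cxcl2, which draw neutrophils through Cxcr2, were at least 333-fold higher and 369.9-fold higher. Arg1 was at least 173-fold higher, Cd274, the checkpoint ligand PD-L1, rose 80.2-fold, and Ccl17 was at least 33.1-fold higher. Each of these genes had no overlap between the groups and was called with TAN replicate 4 alone. Ccl2 was at least 20.9-fold higher, and Ccl3, Ccl5, Icam1 and Tnf rose 149.55-fold, 21.2-fold, 8.72-fold and 5.07-fold (limma adjusted p from 8.34e-11 to 0.000503), the first limited by the top of the scale on TAN replicate 4. S100a8 stayed near the top of the scale in all groups (77.4% or more of the highest signal of each array), which limits what its differences can show, and between TAN and NN it changed little (-0.07, SE 0.09, adjusted p = 0.485), with a sign that turned with median scaling (0.05) and with TAN replicate 4 alone (0.03).

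Of 24 chemokine ligands 18 rose and 3 fell in TANs (18 and 3 adjusted over the list alone), with a median change of 4.93 or 4.46 with members at their bounds (camera adjusted p = 1.29e-06). Of 33 cytokines and growth factors 25 rose and 4 fell (25 and 4 adjusted over the list alone; camera adjusted p = 0.000145), with Il1a, an interleukin that starts inflammation, at least 51.1-fold higher. Class II presentation and costimulation had 14 up and 1 down of 16 (14 and 1 adjusted over the list alone; median 3.81, camera adjusted p = 9.56e-08), with H2-Eb1, a class II chain, up 21.4-fold. Dendritic cell markers had 6 up and 0 down of 8 (7 and 0 adjusted over the list alone; median 2.22, or 1.97 with members at their bounds; camera adjusted p = 0.0091, adjusted p = 0.0747 with an estimated correlation). NF-kB targets had 21 up and 1 down of 24 and immediate early genes 28 up and 1 down of 31 (21 and 1, and 29 and 1, adjusted over each list alone; camera adjusted p = 3e-08 and 5.98e-08). Tnfaip3, an inhibitor of NF-kB signalling, rose 48.0-fold and Atf3, a stress-induced transcription factor, 152-fold. Hypoxia and glycolysis had 18 up and 5 down of 28, angiogenesis and matrix remodelling 22 up and 4 down of 31, and suppressive and alternative activation genes 20 up and 5 down of 28 (the same counts adjusted over each list alone; camera adjusted p = 0.00291, 0.00156 and 7.46e-05). Slc2a1, the glucose transporter Glut1, rose 19.9-fold, Mmp12, a macrophage elastase, was at least 121-fold higher, and Trem2, a lipid-sensing receptor of macrophages, rose 56.7-fold. These 8 lists held with an estimated correlation (adjusted p from 0.00476 to 0.0286). Interferon-stimulated genes had 27 up and 3 down of 39 (27 and 4 adjusted over the list alone; camera adjusted p = 3.68e-05, adjusted p = 0.299 with an estimated correlation), and lysosomal genes 21 up and 2 down of 31 (21 and 2 adjusted over the list alone; camera adjusted p = 0.000349, adjusted p = 0.0688 with an estimated correlation). Class I presentation had 9 up and 6 down of 19 (9 and 6 adjusted over the list alone), with a median of 0.22 that turned to -0.02 with median scaling and to -0.64 without TAN replicate 4 (camera adjusted p = 0.423), and passed as higher with that array alone (median 1.47, adjusted p = 1.51e-05, adjusted p = 0.0575 with an estimated correlation).

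Granulocyte precursor markers were lower in TANs, 15 of 15 measured (15 adjusted over the list alone; median -5.34, or -5.09 with members at their bounds; camera adjusted p = 1.31e-10, adjusted p = 0.0218 with an estimated correlation). Mpo fell 62.8-fold, Camp, the antimicrobial cathelicidin of specific granules, fell 59.3-fold, and Fcnb, a ficolin of immature neutrophils, was at least 75.3-fold lower. Granule proteins had 2 up and 22 down of 30, and cytoskeleton and migration genes 3 up and 29 down of 37 (2 and 22, and 4 and 29, adjusted over each list alone; camera adjusted p = 4.33e-08 and 1.29e-06, held with an estimated correlation at 0.0222 and 0.0150). Cell cycle genes had 0 up and 21 down of 29 (0 and 22 adjusted over the list alone; camera adjusted p = 1.29e-06, adjusted p = 0.179 with an estimated correlation), with Kif11, a mitotic kinesin, at least 7.77-fold lower.

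Markers of other cell types moved with these groups. All 12 measured erythroid markers fell (12 adjusted over the list alone; median -4.99, camera adjusted p = 7.83e-10, held with an estimated correlation at 0.00476), with Slc4a1, the anion exchanger of red cells, at least 507-fold lower. Platelet markers had 0 up and 8 down of 10, and eosinophil, basophil and mast cell markers 1 up and 9 down of 11 (0 and 8, and 1 and 9, adjusted over each list alone; camera adjusted p = 5.28e-05 and 9.99e-05, adjusted p = 0.0747 and 0.139 with an estimated correlation). Prg2, the eosinophil major basic protein, fell 291-fold. B cell markers had 0 up and 7 down of 10 and endothelial markers 1 up and 9 down of 12 (0 and 7, and 1 and 9, adjusted over each list alone). Their medians were -1.97 and -1.23, or -1.67 and -1.11 with members at their bounds (camera adjusted p = 0.0104 and 0.00907, adjusted p = 0.453 and 0.339 with an estimated correlation). Macrophage and monocyte markers had 9 up and 2 down of 16 (9 and 2 adjusted over the list alone; median 1.92, camera adjusted p = 0.0304, adjusted p = 0.5003 with an estimated correlation), with Ms4a7, a membrane protein of macrophages, up 17.2-fold. Without TAN replicate 4 their median was 1.25 and the call was lost (adjusted p = 0.516), and with that array alone the median was 3.51, with 12 up and 1 down (adjusted p = 1.76e-06, adjusted p = 0.1297 with an estimated correlation). Epithelial and mesothelial markers had 7 up and 1 down of 13 (7 and 1 adjusted over the list alone; camera adjusted p = 0.0309, adjusted p = 0.299 with an estimated correlation), with Krt8, a keratin of simple epithelia, up 46.3-fold and Msln, mesothelin, at least 9.42-fold higher.

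In total 6603 of 9523 genes were called between TAN and NN, 3742 up and 2861 down, of which 2288 and 1897 changed 2-fold or more (1879 and 2105 with median scaling). Among 2522 genes with several probes, 348 (13.8%) had probes called in opposite directions. The groups did not overlap for 51.8% of genes, where chance gives 1.67%. TAN replicate 4 alone called 4731 genes, 3996 of them the same way, and at the preset correlation called each list given above as called, in the same direction. With an estimated correlation and that array alone granule proteins and cytoskeleton genes lost their call (adjusted p = 0.0514 and 0.0521), while lysosomal genes were called (adjusted p = 0.0488). Camera called 25 of 34 lists at the preset correlation and 12 with an estimated one. Against only the 5 NN arrays of the TAN batch 6325 genes were called, and with batch as a term in the model 6419.

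SM16 minus NN sets tumour neutrophils under TGF-beta receptor inhibition against naive marrow neutrophils. Ccl8, a chemokine for monocytes, was at least 947-fold higher, at 15.36 ± 0.14 (SD, n = 5) against 5.13 ± 0.32 (SD, n = 7, detected on 2 arrays; limma adjusted p = 2.34e-18). Its probe read up to 75.5% of the highest signal of an SM16 array. Before background correction it read 36250 to 48451 on the SM16 arrays and 75.2 to 144 on the NN arrays, so the bound depends on that correction. Ccl12 and Ccl7 were at least 630.3-fold and at least 411-fold higher. Cxcl13 was at least 277-fold higher (13.56 ± 0.13 against 4.49 ± 0.07). Ccl17 was at the level of naive neutrophils (4.63 ± 0.13 against 4.54 ± 0.22), with neither group above background (0.08, SE 0.26, adjusted p = 0.796). Ccl3 rose 400.02-fold, a value limited by the top of the scale, Ccl2 was at least 92.6-fold higher, and Icam1, Tnf and Ccl5 rose 29.3-fold, 20.3-fold and 12.5-fold. Arg1 was at least 339.6-fold higher and Clec10a rose 100.3-fold. Among the genes that fell, Elane, the neutrophil elastase, was at least 70.7-fold lower and Mpo at least 141-fold lower. S100a8 changed by -0.04 (SE 0.08, adjusted p = 0.679), and by 0.01 without SM16 replicate 4.

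By list, 19 of 24 chemokine ligands rose and 3 fell (19 and 3 adjusted over the list alone; median 5.59, camera adjusted p = 1.77e-07), class II presentation had 14 up and 1 down of 16 (14 and 2 adjusted over the list alone; camera adjusted p = 9.51e-08), and suppressive and alternative activation genes had 22 up and 4 down of 28 (23 and 4 adjusted over the list alone; camera adjusted p = 1.29e-06). Granulocyte precursor markers fell in 15 of 15, erythroid markers in 12 of 12, and granule proteins had 4 up and 22 down of 30 (the same counts adjusted over each list alone; camera adjusted p = 1.46e-09, 1.61e-09 and 6.78e-07). These 6 lists held with an estimated correlation (adjusted p from 0.00136 to 0.0310). Class I presentation had 13 up and 0 down of 19 (13 and 0 adjusted over the list alone; camera adjusted p = 0.0004, adjusted p = 0.174 with an estimated correlation), and cytosolic ribosomal proteins 31 up and 0 down of 40 (32 and 0 adjusted over the list alone; median 0.64, camera adjusted p = 4.86e-05, adjusted p = 0.285 with an estimated correlation). Cell cycle genes had 0 up and 25 down of 29 (0 and 26 adjusted over the list alone; camera adjusted p = 9.34e-07, adjusted p = 0.173 with an estimated correlation). Macrophage and monocyte markers had 15 up and 1 down of 16 (15 and 1 adjusted over the list alone; median 3.90, camera adjusted p = 3.54e-06, adjusted p = 0.158 with an estimated correlation), with Apoe, an apolipoprotein secreted by macrophages, up 32.3-fold. Dendritic cell markers had 5 up and 0 down of 8 (5 and 0 adjusted over the list alone; median 1.47, or 1.22 with members at their bounds; camera adjusted p = 0.0156, adjusted p = 0.0978 with an estimated correlation). Epithelial and mesothelial markers had 9 up and 1 down of 13 (9 and 1 adjusted over the list alone; camera adjusted p = 0.0139, adjusted p = 0.223 with an estimated correlation), with Krt8 up 28.7-fold. B cell markers had 0 up and 7 down of 10, platelet markers 1 up and 9 down of 10, and eosinophil, basophil and mast cell markers 0 up and 10 down of 11 (the same counts adjusted over each list alone). Their medians were -1.91, -4.64 and -2.20, or -1.89, -4.60 and -1.85 with members at their bounds (camera adjusted p = 0.01002, 0.000155 and 8.15e-05, adjusted p = 0.421, 0.0978 and 0.126 with an estimated correlation). Endothelial markers had 3 up and 4 down of 12 (3 and 4 adjusted over the list alone; median 0.27, camera adjusted p = 0.878).

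In total 6146 genes were called between SM16 and NN, 3130 up and 3016 down, of which 1853 and 1718 changed 2-fold or more. With median scaling the majority turned (2775 up and 3122 down, 1680 and 1905 at 2-fold or more), as it did with the mean of all probes of a gene (3038 up and 3106 down). Among 2522 genes with several probes, 59 (2.34%) had probes called in opposite directions. The groups did not overlap for 54.1% of genes, where chance gives 0.253%. Camera called 25 of 34 lists, and 14 with an estimated correlation. Against the 5 NN arrays of the SM16 batch 5875 genes were called, and with batch as a term 5959.

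G-MDSC minus NN asks how splenic neutrophils of tumour-bearing mice differ from naive marrow neutrophils. Immediate early genes and the chemokines Cxcl2, Ccl3 and Ccl4 were higher in the spleen. Fosb, a subunit of the AP-1 transcription factor, was at least 121-fold higher (12.56 ± 1.19, SD, n = 4, against 5.24 ± 0.74, SD, n = 7, detected on 2 arrays; limma adjusted p = 8.24e-12), and Egr1, an early growth response factor, rose 67.8-fold, to 77.1% to 87.6% of the highest signal of each G-MDSC array, where the scale limits the fold. Cxcl2, Ccl3 and Ccl4 rose 121-fold, 80.1-fold and 56.2-fold. Ccl5, Icam1 and Tnf rose 14.4-fold, 5.91-fold and 5.04-fold. Arg1 (0.18, SE 0.27, adjusted p = 0.613) and Ccl17 (0.38, SE 0.27, adjusted p = 0.276) had no call. Ccl2 stood at 5.61 ± 1.10 against 4.61 ± 0.21, undetected on every NN array (adjusted p = 0.0703), and passed the threshold without G-MDSC replicate 2 (1.25, adjusted p = 0.0439) or 3 (1.31, adjusted p = 0.0323). S100a8 fell by 0.24 (SE 0.08, adjusted p = 0.0194), a call lost without G-MDSC replicate 2 (-0.18, adjusted p = 0.108) and against the NN arrays of the same batch (-0.22, adjusted p = 0.251). That call was also lost with median scaling (-0.11, adjusted p = 0.440) and with the replicate block (-0.23, adjusted p = 0.0561).

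Of 31 immediate early genes 25 rose and 0 fell, and of 24 NF-kB targets 22 rose and 0 fell (the same counts adjusted over each list alone; medians 2.06 and 2.14; camera adjusted p = 6.68e-14 and 1.49e-13). Nfkbiz, an inducible nuclear regulator of NF-kB targets, rose 16.03-fold. Class II presentation rose in 16 of 16 (16 adjusted over the list alone; camera adjusted p = 4.31e-13), with Ciita, the class II transactivator, up 12.4-fold. Dendritic cell markers had 6 up and 0 down of 8 (7 and 0 adjusted over the list alone; median 1.26, camera adjusted p = 0.000527), and phagocytic and pattern recognition receptors had 20 up and 0 down of 30 (21 and 0 adjusted over the list alone; camera adjusted p = 3.77e-08), with Tlr1, a receptor of bacterial lipopeptides, up 14.5-fold. These 5 lists held with an estimated correlation (adjusted p from 0.0104 to 0.0339). Cytokine and chemokine receptors had 19 up and 1 down of 30 and interferon-stimulated genes 25 up and 0 down of 39 (19 and 2, and 27 and 0, adjusted over each list alone; camera adjusted p = 0.000263 and 5.08e-10, adjusted p = 0.0691 and 0.150 with an estimated correlation). Chemokine ligands had 11 up and 5 down of 24 (12 and 5 adjusted over the list alone; median 0.65, camera adjusted p = 0.0318, adjusted p = 0.215 with an estimated correlation). That call was lost without G-MDSC replicate 4 (median 0.60, adjusted p = 0.0626) and against NN of the same batch (0.55, adjusted p = 0.0681). It was also lost with median scaling (0.69, adjusted p = 0.198), without background correction (0.30, adjusted p = 0.06495) and in the authors' table (0.37, adjusted p = 0.0585).

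Granulocyte precursor markers fell in 13 of 15 (13 adjusted over the list alone; median -2.98, camera adjusted p = 4.43e-09, held with an estimated correlation at 0.0427), among them Mpo, down 31.8-fold. Erythroid markers fell in 12 of 12 and platelet markers in 9 of 10 (12 and 9 adjusted over each list alone; camera adjusted p = 1.32e-13 and 1.13e-08, held with an estimated correlation at 0.00198 and 0.0290), with Slc4a1 down 289-fold and Ppbp, a platelet chemokine precursor, at least 260-fold lower. Eosinophil, basophil and mast cell markers had 0 up and 9 down of 11, fibroblast markers 0 up and 9 down of 12 and endothelial markers 0 up and 10 down of 12 (the same counts adjusted over each list alone). Their medians were -1.68, -1.73 and -1.95, and those of fibroblast and endothelial markers -1.03 and -1.53 with members at their bounds (camera adjusted p = 3.07e-05, 0.000387 and 0.000153, adjusted p = 0.126, 0.1598 and 0.162 with an estimated correlation). Cell cycle genes had 1 up and 25 down of 29 (1 and 25 adjusted over the list alone; median -2.61, camera adjusted p = 9.09e-14, adjusted p = 0.0691 with an estimated correlation), with Top2a, a topoisomerase of dividing cells, down 14.2-fold. Granule proteins had 4 up and 17 down of 30 (4 and 17 adjusted over the list alone; camera adjusted p = 0.000285, adjusted p = 0.126 with an estimated correlation). Oxidative phosphorylation had 0 up and 28 down of 57 (0 and 28 adjusted over the list alone; camera adjusted p = 0.00079, adjusted p = 0.306 with an estimated correlation), with a median of -0.36 that turned to 0.05 with median scaling. Hypoxia and glycolysis had 7 up and 10 down of 28 (7 and 10 adjusted over the list alone; camera adjusted p = 0.778), with a median of -0.01 that was 0.14 with median scaling and turned sign, up to 0.06, without NN replicate 2, 4 or 7 or any single G-MDSC array. Macrophage markers had 5 up and 4 down of 16 (5 and 4 adjusted over the list alone), with a median of 0.03 and a mean of -0.23 (camera upward, adjusted p = 0.991), and a median down to -0.06 without NN replicate 5 or 7 or G-MDSC replicate 2 or 3. T and NK cell markers had a median of 0.58 and 2 up and 2 down of 13 (2 and 2 adjusted over the list alone; camera adjusted p = 0.629), and a median of -0.27 without G-MDSC replicate 1. B cell markers had 1 up and 2 down of 10 (1 and 2 adjusted over the list alone; median -0.52, camera adjusted p = 0.458) and were called lower without that array at the preset correlation (-1.30, adjusted p = 0.00137).

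In total 4373 genes were called between G-MDSC and NN, 2138 up and 2235 down, of which 962 and 1037 changed 2-fold or more. Among 2522 genes with several probes, 37 (1.47%) had probes called in opposite directions. The groups did not overlap for 38.3% of genes, where chance gives 0.606%. Camera called 23 of 34 lists, and 8 with an estimated correlation. Against only the 2 NN arrays of the G-MDSC batch 2581 genes were called (1215 up and 1366 down, 2487 of them called the same way with all NN arrays), and with batch as a term 3043. Median scaling moved the share of calls that were up from 48.9% to 66.9%.

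TAN minus G-MDSC asks how tumour neutrophils differ from splenic neutrophils of tumour-bearing mice. Ccl8 was at least 381-fold higher on the background-corrected scale, at 14.05 ± 0.60 (SD, n = 3) against 4.98 ± 0.55 (SD, n = 4, detected on 1 array; limma adjusted p = 6.41e-15). Before that correction its probe read 13301 to 25112 on the TAN arrays and 106 to 144 on the G-MDSC arrays. Ccl7 was at least 238-fold higher and Arg1 at least 178-fold higher. Ccl17 and Ccl2 were at least 33.9-fold and at least 15.1-fold higher. Trem2 rose 57.5-fold and Mmp14, a membrane-bound matrix metalloprotease, 64.7-fold. Gp2, a glycoprotein of zymogen granules, was at least 13.7-fold lower in TANs and Camp fell 23.4-fold. Ccl5 (0.55, SE 0.38, adjusted p = 0.212) and Ccl3 (0.90, SE 0.53, adjusted p = 0.148) had no call. Both passed the threshold without G-MDSC replicate 1 (0.87 and 1.34), Ccl5 also without TAN replicate 4 (0.92) and Ccl3 also with that array alone (2.28), where Ccl5 gave -0.19. Tnf changed by 0.01 (SE 0.57, adjusted p = 0.993), by -0.39 with median scaling, by -1.10 without TAN replicate 4 (adjusted p = 0.0131), by -0.28 and -0.11 without G-MDSC replicates 2 and 4, and by 2.22 with that array alone. Icam1 changed by 0.56 (SE 0.44, adjusted p = 0.279), by 1.11 without TAN replicate 1 (adjusted p = 0.0385), by -0.40 without TAN replicate 4 and by 2.48 with TAN replicate 4 alone. S100a8 changed by 0.17 (SE 0.10, adjusted p = 0.141). Mpo fell 1.97-fold (adjusted p = 0.0195), a call lost without TAN replicate 4 (-0.84, adjusted p = 0.0565) or G-MDSC replicate 1 (-0.59, adjusted p = 0.0741) and with TAN replicate 4 alone (-1.26, adjusted p = 0.0532). It was also lost without background correction and in the authors' table (adjusted p = 0.0681 and 0.0583). Arhgap45 was the gene with the largest rise, but its probe read 10.3 to 17.7 on every array of the G-MDSC batch, NN replicates 6 and 7 included, and 3310.5 or more on all others. With batch as a term it changed by -0.42 (adjusted p = 0.266).

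Of 24 chemokine ligands 20 rose and 1 fell (20 and 1 adjusted over the list alone; median 3.25, or 2.95 with members at their bounds; camera adjusted p = 2.08e-07). Hypoxia and glycolysis had 20 up and 6 down of 28 (20 and 6 adjusted over the list alone; camera adjusted p = 0.00056), with Egln3, a hypoxia-induced prolyl hydroxylase, up 10.4-fold. Angiogenesis and matrix remodelling had 20 up and 4 down of 31 (20 and 5 adjusted over the list alone; camera adjusted p = 0.00412) and suppressive and alternative activation genes 21 up and 3 down of 28 (21 and 3 adjusted over the list alone; camera adjusted p = 9.34e-05). These 4 lists held with an estimated correlation (adjusted p from 0.00587 to 0.0388). Lysosomal genes had 20 up and 4 down of 31 and granule proteins 1 up and 17 down of 30 (the same counts adjusted over each list alone; camera adjusted p = 0.000411 and 1.16e-05, adjusted p = 0.101 and 0.0993 with an estimated correlation). Mature neutrophil markers had 4 up and 11 down of 21 (4 and 12 adjusted over the list alone; median -0.67, camera adjusted p = 0.0126, adjusted p = 0.323 with an estimated correlation), with Itgam, the integrin CD11b, down 6.56-fold, and lost the call with TAN replicate 4 alone (median -0.35, adjusted p = 0.112). Class II presentation had 11 up and 2 down of 16 (12 and 2 adjusted over the list alone). Its camera adjusted p was 0.0198, and 0.485 with an estimated correlation. The call was lost without TAN replicate 4, where the median was 1.12 (adjusted p = 0.123). Immediate early genes had 10 up and 7 down of 31 (10 and 7 adjusted over the list alone), with a median of 0.05, a downward camera test (adjusted p = 0.791) and a median of -0.15 with median scaling. Their median also turned, down to -0.09, without any single TAN array or G-MDSC replicate 2 or 3.

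Macrophage and monocyte markers had 11 up and 2 down of 16 between TAN and G-MDSC (11 and 2 adjusted over the list alone; median 1.82, camera adjusted p = 0.00555, adjusted p = 0.567 with an estimated correlation), with Ms4a7 up 29.8-fold. Epithelial and mesothelial markers had 9 up and 0 down of 13 (9 and 0 adjusted over the list alone; camera adjusted p = 0.00989, adjusted p = 0.323 with an estimated correlation), with Krt8 at least 54.6-fold higher. Fibroblast markers had 7 up and 0 down of 12 (7 and 0 adjusted over the list alone; median 1.58, or 1.10 with members at their bounds; camera adjusted p = 0.0204, adjusted p = 0.567 with an estimated correlation), with Dcn, the matrix proteoglycan decorin, at least 6.19-fold higher. Without TAN replicate 4 the macrophage and fibroblast calls were lost (medians 1.33 and 1.73, adjusted p = 0.346 and 0.0830). With that array alone the medians were 3.20 and 0.96, and both were called at the preset correlation but not with an estimated one. The fibroblast call was also lost without background correction (adjusted p = 0.0539). B cell markers had 0 up and 5 down of 10 (0 and 4 adjusted over the list alone; median -1.21, or -0.96 with members at their bounds; camera adjusted p = 0.0204, adjusted p = 0.607 with an estimated correlation). That call was lost without TAN replicate 4 (-1.06, adjusted p = 0.0927) and with median scaling (-1.73, adjusted p = 0.0643). Granulocyte precursor markers had 0 up and 11 down of 15 (0 and 12 adjusted over the list alone; median -1.38, camera adjusted p = 1.01e-05, adjusted p = 0.127 with an estimated correlation).

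In total 6022 genes were called between TAN and G-MDSC, 3585 up and 2437 down, of which 2274 and 1542 changed 2-fold or more. Among 2522 genes with several probes, 292 (11.6%) had probes called in opposite directions. The groups did not overlap for 49.6% of genes, where chance gives 5.71%. TAN replicate 4 alone called 4174 genes, 3283 of them the same way, and at the preset correlation called each list given above as called, in the same direction, except mature neutrophil markers. Camera called 18 of 34 lists with all arrays, and 5 with an estimated correlation. The 2 groups lie in different batches. With batch as a term, read from the NN arrays, 3885 genes were called (2256 up and 1629 down, 3678 of them as before). With that term fibroblast markers (median 1.39, adjusted p = 0.0632), Mpo (-1.11, adjusted p = 0.105) and Itgam (-1.58, adjusted p = 0.0598) lost their call, and Tnf and Arhgap45 turned to -0.58 and -0.42. Median scaling moved the share of calls that were up from 59.5% to 41.2%.

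The changes of TAN and SM16 against naive neutrophils were largely shared. Across the 9523 genes the log2 changes of TAN minus NN and SM16 minus NN correlated at r = 0.824, where simulated groups without change gave 0.353 from the shared NN arrays. Both called 2490 genes up, with 1229.9 given by independent lists (the median was 2255 with NN split in 3 and 4 arrays), and 2113 down (906 and 1876), and 149 in opposite directions. TAN minus NN and G-MDSC minus NN correlated at 0.565 (0.330 simulated), with 1418 genes up in both (840.1 from independent lists, 1210 with NN split), 1268 down in both (671 and 1106) and 565 in opposite directions. The correlations with TAN replicate 4 alone were 0.929 and 0.626.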

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

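No test in this part was chosen after its result was seen. Each NN, G-MDSC and SM16 array was set against the others of its group. The measure was the gap to its nearest neighbour relative to the range of the group, which marks about 1 in 20 groups by chance. The 3 TAN arrays were too few for the test and were not screened. Of 336 groups of values, 22 were marked where chance gives 16.8, and no explanation was tested for them.

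Marked arrays differed most in the G-MDSC group. Values of lists are median log2 deviations from the mean of the 4 group means. G-MDSC replicate 1 had B cell markers at 3.07 (next array -0.17) and T and NK cell markers at 2.84 (next -0.24). Its eosinophil, basophil and mast cell markers stood at 0.59 and its cytosolic ribosomal proteins at 0.31. Each was the high end of its group. On the same array Ccl4 stood at 14.72, Cxcl2 at 14.67, Rps7 at 13.95 and Dusp4 at 6.12, above the other G-MDSC arrays, and Ms4a7 at 5.59, below them. Its mean correlation with its own group, across genes, was 0.960 (next 0.980). G-MDSC replicate 4 was high for lysosomal genes (-0.34, next -0.54), Esam (7.22) and Kif11 (5.78).

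In the SM16 group, replicate 3 was low in its mean correlation with its group (0.976, next 0.983) and in hypoxia and glycolysis (0.41, next 0.60), and high for Nfkbiz (14.33). S100a8 was low on SM16 replicate 4 (15.59) and Cxcl1 high on SM16 replicate 5 (13.13). Among naive neutrophils, replicate 4 was high for the TGF-beta pathway and response (-0.12, next -0.22) and for macrophage and monocyte markers (-0.99, next -1.42), and replicate 6 for Ccl2 (5.04) and Ccl7 (5.02).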

How the results depend on the processing

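Median scaling of single genes and lists, TAN replicate 4 alone, the array batch as a term and the NN arrays of the same batch were tests chosen only after the result was seen.

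Apart from the genes reported whatever their values, named genes were chosen as called with large changes in these same data. That they keep direction and call is thus partly fixed beforehand, also with arrays left out, and does not show how other genes hold. Of 280 log2 changes of named genes, those that kept direction and call numbered 280 without a filter, 277 without background correction, 276 with the authors' table, 273 with median scaling and 276 with the replicate number as a block. With TAN replicate 4 alone 153 of 189 did (22 weaker, 3 stronger, 11 reversed), against NN of the same batch 160 of 161, and with batch as a term 48 of 52. Of 90 list results 88 were kept without a filter, 87 without background correction, 88 with the authors' table, 80 with median scaling, 87 with the block, and 50 with an estimated correlation, where 40 lost the call. With TAN replicate 4 alone 40 of 53 list results were kept, against NN of the same batch 59 of 60, and with batch as a term 13 of 14. Without a filter cytokine and chemokine receptors turned (-0.026) in SM16 minus TAN. The cause was not tested.

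Without background correction the genes called at 2-fold or more numbered 830, 2663, 2308, 1165 and 2083 in SM16 minus TAN, TAN minus NN, SM16 minus NN, G-MDSC minus NN and TAN minus G-MDSC, and the shared changes correlated at 0.844 and 0.602. With the authors' table the 2-fold counts were 966 in SM16 minus TAN, 1261 in G-MDSC minus NN and 2289 in TAN minus G-MDSC, and Tnf changed by -0.019 in the last. The share of 2-fold calls in SM16 minus TAN that were up was 73.7% without background correction, 70.5% with the authors' table and 44.4% with array weights, against 56.0%. Array weights called 7461 genes between SM16 and TAN, 3226 at 2-fold, with a weight estimate that did not fully converge. A fit of only the 2 groups called 2365, with 723 up and 725 down at 2-fold.

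Median scaling shifted the median of all genes by -0.11 in TAN minus NN, 0.23 in G-MDSC minus NN and -0.34 in TAN minus G-MDSC. It turned the ribosomal proteins (-0.21), S100a8 (-0.26), receptors (-0.092) and lysosomal genes (-0.25) in SM16 minus TAN, class I presentation (-0.021) and S100a8 (0.047) in TAN minus NN, oxidative phosphorylation (0.054) and hypoxia (0.14) in G-MDSC minus NN, and immediate early genes (-0.15) and Tnf (-0.39) in TAN minus G-MDSC. The up-shares at 2-fold were 66.4% in G-MDSC minus NN and 37.2% in TAN minus G-MDSC.

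Whether the replicate numbers pair the samples was not decided. Deviations from the group means correlated at -0.25 to 0.20 between arrays with the same number. In TAN minus G-MDSC 2 of 3 TAN arrays correlated best with the array of their own number, in TAN minus NN 1 of 3, and 0 in the other comparisons. The TAN deviations also hold the split of TAN replicates 1 and 2 from TAN replicate 4. As a block the replicate numbers gave 3844, 6057, 5788, 4290 and 5802 genes, with S100a8 at -0.021 and a call of the ribosomal proteins (0.088, adjusted p = 0.0377) in SM16 minus TAN, and hypoxia at 0.017 and macrophage markers at -0.092 in G-MDSC minus NN.

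TAN replicate 4 alone called 451 genes between SM16 and TAN, 286 at 2-fold, and reversed Tnf (-0.21), Icam1 (-0.17), S100a8 (-0.070), Arg1 (-0.17), H2-T23 (-0.0029), Rps7 (-0.22), Tuba1b (-0.11), Ltb (-1.10), receptors (-0.34), oxidative phosphorylation (0.11) and T and NK cell markers (0.0033). It reversed S100a8 (0.031) and Rps7 (0.62) in TAN minus NN and Ccl5 (-0.19) in TAN minus G-MDSC, and the shared changes correlated at 0.929 and 0.626. With batch as a term TAN minus G-MDSC had 3885 genes, Arhgap45 at -0.42 and Tnf at -0.58. Against NN of the same batch G-MDSC minus NN had 2581 genes. With NN split, the shared correlation of TAN and SM16 was 0.816 at the median.

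With each array left out in turn the count between SM16 and TAN ranged from 2276 (without TAN replicate 1) to 6018 (without TAN replicate 4), and at 2-fold from 1210 to 3262. In SM16 minus TAN S100a8 ranged from -0.010 to 0.086, ribosomal proteins from -0.039 to 0.071, lysosomal genes from -0.054 to 0.10 and oxidative phosphorylation from -0.31 to 0.061. Class I presentation in TAN minus NN ranged from -0.64 to 0.59 and S100a8 in SM16 minus NN from -0.063 to 0.0063. In G-MDSC minus NN hypoxia ranged from -0.044 to 0.056, macrophage markers from -0.056 to 0.13 and T and NK cell markers from -0.27 to 0.96. In TAN minus G-MDSC immediate early genes ranged from -0.090 to 0.11, Tnf from -1.10 to 0.60 and Icam1 from -0.40 to 1.11. In all 2613 of 2642 gene values and 844 of 879 list values kept direction and call.

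The BeadChip as a block was not run, since the columns do not give it, nor the series table, whose values are the same. Signal over background limits the dim genes, for which only bounds are given.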

Other observations

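Of the tests in this part, those of expression by neutrophils alike in every preparation, of gene-level differences, of shifted lines of the table, of a wrong label and of a lower share of neutrophils were chosen only after the result was seen, as were all values with TAN replicate 4 alone and with the array batch.

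Among genes not described above, Dusp4, a phosphatase of MAP kinases, fell 4.30-fold after SM16 (log2 change -2.11, SE 0.27; -1.87 with TAN replicate 4 alone). Ier2, an immediate early gene, was at least 4.13-fold lower (-1.76 with TAN replicate 4 alone) and Ass1, which makes the precursor of arginine, fell 7.68-fold (-2.94, SE 0.41; -2.45 with that array). In splenic neutrophils Igfbp6, a binding protein of insulin-like growth factors, was at least 44.2-fold higher than in naive neutrophils and Ambp, a plasma protein precursor, at least 34.7-fold. Clec4n, the fungal receptor Dectin-2, rose 20.6-fold and Socs3, an inhibitor of cytokine signalling, 15.9-fold.

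Genes of the hair follicle were high on the SM16 arrays. Of 34 other hair genes, listed before their values were seen, 55.9% rose in SM16 minus TAN, and Krt75 fell. The probes with the highest signal on the SM16 arrays, which does not rank transcripts by abundance, were those of Krt86 (mean level 9.62, log2 change 0.21, and 9.94 in NN), Krtap13-1 (8.14, change 3.72), Krt72 (8.12, change 3.02) and Krt26 (8.02, change 2.87). Hair follicle tissue in the SM16 preparations is a candidate source: most of the genes rose, but the bound set for it also required that none fell, so it stays open. With TAN replicate 4 alone 14.7% passed the test in that comparison with a single array, while the median change of the 34 genes was 0.73, as with all TAN arrays (0.73). Whole skin stays open too, with a median change of 0.55 over 19 genes of the epidermis between follicles. Expression by the neutrophils, alike in every SM16 preparation, is argued against by a range of 4.50 log2 between SM16 arrays in the median of the 10 named hair genes, and expression that differs between preparations was not tested.

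TAN replicates 1 and 2 stood apart from TAN replicate 4. Gene-level differences between the preparations or their cells would move the probes of a gene together, but the probes of 27.2% of genes parted on the lower of both arrays, against 1.54% on the highest other array. Shifted lines in the deposited table would lose most bright probes within a block, and the highest share in any block was 20%. A wrong label, with TAN replicate 4 an SM16 sample, is argued against by 451 genes called between it and the SM16 arrays, 5.01 times the highest number called between an SM16 array and the other 4. Against 4 SM16 arrays, the like comparison, TAN replicate 4 gave 324 to 632 genes, where that highest number was 90. RNA or array quality was not tested and stays open.

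Macrophage transcripts were high in the tumour preparations. On a second list of 30 macrophage genes, written before its values were seen, 25 rose in SM16 minus NN, with a median change of 2.12. Among its risers the probes with the highest signal, which likewise does not rank abundance, were those of Slc11a1 (mean level 14.25 on the SM16 arrays, log2 change 0.57, and 13.68 in NN), Ms4a6d (14.22, change 6.28), Pltp (13.25, change 5.91) and Gas6 (12.88, change 5.25). From the median change of the list, macrophages in the tumour preparations are a candidate source. A lower share of neutrophils would raise every other cell type alike, while the macrophage markers lay 2.64 log2 above the highest median of 5 other cell types. These medians also depend on which cells the naive marrow preparations held, so the test does not decide the question. Expression of these genes by neutrophils in the tumour was not tested and stays open, and the labels name no sort or gate that would remove macrophages.

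Chance was tested by counting called genes in other splits of the same arrays. Of the splits run only the real one gave as many genes in each comparison, which argues against chance alone. It does not exclude chance, since the smallest share that TAN and G-MDSC could reach was 1 of 35. Nor does it address a structure of the samples other than the groups. The splits run were all 56 for SM16 and TAN and all 35 for TAN and G-MDSC. They were 100 drawn from 120, 792 and 330 for TAN and NN, SM16 and NN, and G-MDSC and NN. Between SM16 and TAN the real split called 4380 genes and the highest of the others called 4339. That split set TAN replicates 1 and 2 and SM16 replicate 3 apart, so the count followed TAN replicates 1 and 2, whose probes parted, and does not tie the genes to the inhibition. TAN replicate 4 alone called 451. Between TAN and NN the real split called 6603 and the highest other 4139 (TAN replicates 1 and 2 with NN replicate 1). Between SM16 and NN the values were 6146 and 3948, between G-MDSC and NN 4373 and 950, and between TAN and G-MDSC 6022 and 4916, the last with G-MDSC replicates 2 to 4 apart.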
